A study of Mus musculus with 9 samples.

How the data were processed

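RNA was measured by strand-specific total RNA sequencing of the membranous labyrinth of the mouse cochlea, the soft tissue inside its bony shell, at postnatal day 28. The labels gave 9 samples in 3 groups with 3 libraries each, described as biological replicates: wild type (WT), homozygous for a humanized MPZL2 gene carrying a nonsense variant, and homozygous treated. Treated animals had received an adeno-associated virus carrying an adenine base editor and a guide RNA through the round window membrane at postnatal day 2. Groups were taken from the sample titles, because the genotype field of the labels counted upward from sample to sample.

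The deposited values were TPM, an abundance scaled by transcript length and library total, in 2 tables with different columns. Per the submitters' processing notes, reads were quantified with kallisto 0.51.0, DESeq was used with no version given, and the genome build was GRCm39. The first deposited table held TPM for 1411 rows in the WT and homozygous libraries, and the second held TPM for 25606 rows in the homozygous and treated libraries. The rule by which the authors chose the rows of the first table is not given in the sources used here. Of its tested genes, 0 had an absolute log2 fold change under 0.2, against 21.5% of the genes of the second table, and the smallest absolute log2 fold change was 0.243. The rank correlation of its row order with the p-values computed here was 0.698. The first table is therefore treated as a list chosen on these samples, and its counts are not independent evidence. Adjusted p-values over such a list are too small, so the threshold does not hold its stated error rate there. TPM keeps no sequencing depth, so the depth is unknown and no interval or detection floor is given. The homozygous libraries had different values in both tables, with a correlation of log2 values of 0.949 for library 1 and a median ratio of 0.856. Tests were therefore made only within a table, and treated libraries were not tested against WT libraries.

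Treated libraries 1 and 2 were close to identical. The spread of their log2 ratio was 0.0643 for genes at 1 to 5 TPM, where pairs of homozygous libraries gave 0.867 to 1.07 and treated libraries 1 and 3 gave 2.04. They differed by less than the noise between other replicates and were counted as 1 sample through their mean TPM, so the treated group had 2 samples. That decision was made after the values had been seen and before any test was run. The fit of all 9 libraries together with a count model, fixed before the data were examined, could not be made on TPM, and the form fixed then for normalized values was used in each table.

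Values of repeated symbols were summed, which left 1410 and 25579 symbols. Genes with at least 1 TPM in at least 3 deposited libraries were tested, 1348 in the first table and 17102 in the second. limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with a mean per group and a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. Errors of means are SD between samples. A gene that loses or gains reads through near-identical copies is named as uncertain.

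Before the data were examined, 26 gene lists were fixed for cell types of the cochlea, other cell types, pathways and RNA quality. They were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Membership of each list among the genes of the first table was tested with Fisher's exact test against the 16413 genes of the second table at 1 TPM or more in 2 homozygous libraries, a test added after the data had been seen. Named genes followed a rule fixed before the data were examined. It took Mpzl2, up to 10 higher and 10 lower genes with the largest fold change past the threshold with no overlap between samples, a mean of at least 1 TPM and an ordinary symbol, and up to 2 higher and 2 lower members of each list with the smallest p. For a list without any, it took the 2 members with the highest mean. The result of 1 gene that the rule named is not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

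The comparison of both contrasts used 1273 genes tested in both tables. Its chance values came from 1000 simulations of unchanged groups that shared the homozygous libraries. The 3 homozygous libraries could not be split into parts of 2 libraries.

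The scripts were tested on simulated data with 200 changed genes. In the homozygous against WT design, run on 1348 genes, 89% of genes with a log2 change of 1 and 100% of genes with a log2 change of 2 were recovered, and 6 of 195 calls were false. In the treated against homozygous design, run on 17102 genes, the shares were 3% and 55%, and 0 of 58 calls were false. With no list changed, camera called 0 of 26 lists. That result does not vouch for the camera p-values of the real lists, whose genes can vary together. In the real data, 3 lists passed camera at the preset correlation for homozygous against WT and 13 for treated against homozygous. With an estimated correlation, 0 lists passed in either comparison.

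Alternatives covered the pseudocount, the filter on low values, a replicate block, a fold threshold, each library left out, and set tests. Leaving out treated library 1 or 2 kept the other of the near-identical pair, so those fits removed no sample. Added after the data had been seen were median-of-ratios scaling, robust moderation, a filter of 5 TPM, the treated libraries as separate samples, treated libraries 1 and 2 left out, removal of the mitochondrially encoded genes, and removal of a trend with transcript length. Transcript lengths were taken from the GENCODE M21 transcripts by symbol and were found for 97.3% of the tested genes of the second table. No coordinates are given, because that annotation belongs to another build than the authors'.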

Results

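RNA from the cochlear membranous labyrinth was compared between 3 WT libraries, 3 libraries from mice homozygous for the humanized nonsense allele of MPZL2, and 3 libraries from homozygous mice treated with a base editor vector. Mpzl2 encodes an adhesion protein of the immunoglobulin superfamily, and MPZL2 variants are known from inherited hearing loss. The design text gave the purpose as finding molecular pathways behind the cochlear histopathology of the variant. The second table summed to between 995747 and 996703 TPM per library, with 16529 to 17281 genes at 1 TPM or more. The first table, a selected part of the genes, summed to between 120756 and 137436 TPM. The depth of the libraries is unknown.

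Mpzl2 was lower in every homozygous library than in every WT library. Its level was 42.1 ± 7.84 TPM in WT (SD, n = 3) and 17.5 ± 5.42 TPM in homozygous libraries (SD, n = 3), a log2 fold change of -1.25 with a standard error of 0.24 (limma adjusted p = 0.0139). Without WT replicate 3 the adjusted p was 0.0544. In the second table Mpzl2 was at 18.2 ± 5.48 TPM in the homozygous libraries (SD, n = 3). The treated libraries had 5.64, 5.62 and 16.3 TPM, and the difference did not pass the test (log2 fold change -0.80, limma adjusted p = 0.335). Reads of the humanized allele may not count to the mouse gene, so these levels do not measure editing.

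**Figure D1:**
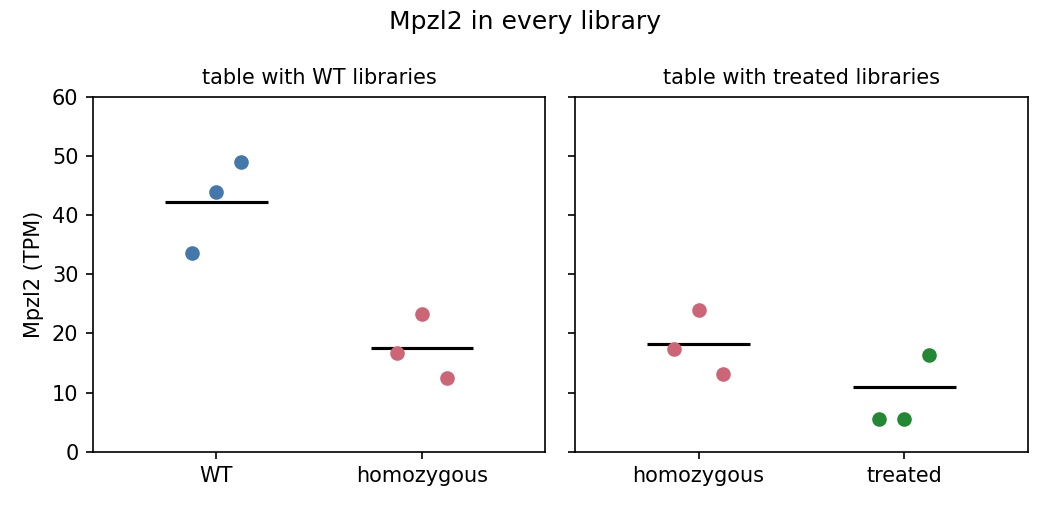
Points give Mpzl2 in TPM in each library, with the table holding WT libraries on the left and the table holding treated libraries on the right, and horizontal lines give group means. The line of the treated group averages the mean of libraries 1 and 2 with library 3; WT libraries lie around 42.1 TPM and homozygous libraries around 17.5 TPM in the left panel.

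The first comparison asked how the homozygous cochlea differs from WT. Genes of the cartilage-type collagens and of the tectorial matrix were lower in the homozygous libraries. Of 10 tested members of the list of tectorial membrane and otic matrix genes, 8 fell and 0 rose, and 8 passed when adjusted over the list alone. Col9a1, a chain of collagen type IX, fell from 295 ± 28.1 to 56.7 ± 5.89 TPM (SD, n = 3 each), a log2 fold change of -2.36 (limma adjusted p = 9.41e-05). Col2a1, the chain of collagen type II, fell from 1273 ± 170 to 318 ± 45.1 TPM (SD, n = 3 each; limma adjusted p = 0.000694). Col9a2, Emilin2, and Tectb, which encodes beta-tectorin of the tectorial membrane, fell with log2 fold changes of -1.65, -1.94 and -1.56. Tectb lost its call in 4 of the 6 fits with 1 replicate left out. Of 13 tested genes of the general extracellular matrix list, 12 fell and 12 passed when adjusted over the list alone. Among them Col3a1 had a log2 fold change of -1.47 and Lamc1, a laminin chain, one of -0.95. The camera adjusted p was 0.00472 for the otic matrix list and 5e-04 for the extracellular matrix list, and for both the adjusted p = 0.431 with an estimated correlation. Because this table is treated as chosen on these samples, these counts are not independent evidence of direction. The genes of the table held 60% of the otic matrix list and 52% of the extracellular matrix list, against 7.8% of all background genes (Fisher's exact test, two-sided, adjusted p = 4.39e-06 and 2.07e-07), and 11 of the 26 lists were over-represented in this way. Fisher's test takes genes as independent, but genes of a list can vary together, and the background was not matched for level. Its p-values can therefore be too small. Bone markers, given here because the dissected tissue borders bone, moved in the same libraries, with 3 lower and 1 higher of 5 tested. Dmp1 and Col1a2 fell with log2 fold changes of -1.31 and -0.98, and Spp1, the gene of osteopontin, rose by 0.74 and lost its call in 4 of the 6 fits.

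Genes of the myelin sheath of peripheral nerve were lower as well. Of 8 tested members of the Schwann cell and myelin list, 6 fell, and 7 did when adjusted over the list alone. Prx, the gene of periaxin, fell from 223 ± 16.1 to 113 ± 22.6 TPM (SD, n = 3 each; limma adjusted p = 0.00847), and Ncmap had a log2 fold change of -0.90. This list had a camera adjusted p of 0.0389, and adjusted p = 0.593 with an estimated correlation. The list lost its call without WT replicate 2 or 3 (adjusted p = 0.0597 and 0.0505) and with fry (adjusted p = 0.0649). Of 5 tested spiral ganglion neuron genes, 4 fell, and 5 did when adjusted over the list alone, with log2 fold changes of -0.49 for the vesicular glutamate transporter Slc17a7 and -0.46 for Stmn2. That list did not pass camera (adjusted p = 0.134), and under median-of-ratios scaling 0 of the 5 genes passed. With 1 replicate left out Slc17a7 lost its call in 4 of 6 fits, Stmn2 in 5 and Ncmap in 3. All 4 tested immediate early genes fell, among them Egr1 and Arc with log2 fold changes of -1.19 and -0.93. The list did not pass camera (adjusted p = 0.114) but passed fry (adjusted p = 0.0378). Under median-of-ratios scaling 2 of the 4 passed, and Egr1 and Arc each lost their call in 4 of the 6 fits with 1 replicate left out.

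Genes of the lateral wall passed in both directions, the higher ones mostly close to the threshold. Of 5 tested stria marginal cell genes 3 rose, among them the endocytic receptor gene Lrp2, from 172 ± 17.01 to 354 ± 173 TPM (SD, n = 3 each; limma adjusted p = 0.04), and Atp13a5 with a log2 fold change of 0.79. This list did not pass camera (adjusted p = 0.0914). Without homozygous replicate 2 the log2 fold changes were 0.57 for Lrp2 and 0.52 for Atp13a5, and Lrp2 kept its call there. With 1 replicate left out Lrp2 lost its call in 4 of 6 fits and Atp13a5 in 5. Of 6 tested genes of spiral ligament fibrocytes, 2 rose and 2 fell. Slc4a11, a membrane transporter, and Apod, the gene of apolipoprotein D, had log2 fold changes of 1.72 and 0.71, while Emilin2, named above, and Otor had -1.94 and -0.88. Sox8 was the 1 of 4 tested basal, root and spindle cell genes that rose, by 0.60 on the log2 scale. That list did not pass camera (adjusted p = 0.112) but passed fry (adjusted p = 0.0447). Sox8 and Apod each lost their call in 5 of those 6 fits and Slc4a11 in 2. Of 6 tested genes of intermediate cells and melanocytes 0 passed limma and 3 had an unadjusted p under 0.05, with Gsta4 at 198 ± 49.7 TPM in WT and 343 ± 157 TPM in homozygous libraries and Kcnj10 at 62.5 ± 7.07 and 80.7 ± 16.9 TPM (SD, n = 3 each). Under median-of-ratios scaling 4 of the 5 marginal, 4 of the 6 intermediate and 3 of the 4 basal, root and spindle cell genes passed as higher. Of 6 supporting cell genes 1 fell, which was Tectb, and under that scaling 1 was also higher. The lists of supporting cells and fibrocytes did not pass, and their measures differed in sign. Supporting cells had a median log2 fold change of -0.07 with camera pointing up (adjusted p = 0.843), and fibrocytes had a median of 0.37 with camera pointing up (adjusted p = 0.563) and fry pointing down (adjusted p = 0.84).

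The other lists had few members in the first table. Oas1a was the 1 of 3 interferon response genes that rose (log2 fold change 0.84), and Manf the 1 of 2 unfolded protein response genes that rose (0.43). The interferon list did not pass camera (adjusted p = 0.112) but passed fry (adjusted p = 0.0378). Ighm, a lymphocyte gene, and Bbc3, a p53 target, were the single tested members of their lists and fell, with log2 fold changes of -0.99 and -1.36. In the 6 fits with 1 replicate left out Manf lost its call in 5, Oas1a and Bbc3 in 4 and Ighm in 3. Of 4 tested junction genes 0 passed limma and 2 had an unadjusted p under 0.05, with Cdh1 at 103 ± 8.94 and 130 ± 30.5 TPM and Ocln at 30.4 ± 1.34 and 39.8 ± 5.07 TPM in WT and homozygous libraries (SD, n = 3 each). Median-of-ratios scaling made 2 of the 4 junction genes and 2 of the 3 interferon response genes pass as higher. The single tested members of the lists of hair cells, skeletal muscle, endothelium and cell cycle did not pass, with log2 fold changes of -0.65 for Ptprq, -0.62 for Ryr1, -0.46 for Cspg4 and 0.93 for Mcm2. The lists of macrophages, neutrophils, erythroid cells, cytokines, mitochondrially encoded genes and oxidative phosphorylation had 0 tested members.

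Outside the lists, the largest falls by log2 fold change were those of Rarres1 (-2.45), Cpz (-2.41), Oc90 (-2.39), an otoconial matrix gene, Gpr132 (-2.01), Col28a1 (-1.78) and Helt (-1.71). The largest rises were those of Ppp1r1a (2.15), Gal3st2 (1.99), Gstm6 (1.80), Prol1 (1.78), Ccr6 (1.63), Aass (1.55) and Mgl2 (1.51). Of these, Ccr6 lost its call in 4 of the 6 fits with 1 replicate left out, and Gpr132, Gal3st2 and Gstm6 in 3. Ppp1r1a, the gene of a protein phosphatase inhibitor, was at 51.7 ± 7.13 TPM in WT and 241 ± 79.8 TPM in homozygous libraries (SD, n = 3 each; limma adjusted p = 0.0031). H2ac19 and H2ac23, histone genes with near-identical copies, also passed and are uncertain. H2ac23 was listed at 0 in the 3 WT libraries and at 12.1, 6.66 and 2.47 TPM in the homozygous libraries.

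Of the 1348 tested genes, 692 passed, 241 higher and 451 lower in homozygous libraries, and 140 of them had an absolute log2 fold change of at least 1. An unadjusted p under 0.05 was reached by 1020 genes, and 77.1% of the genes had no overlap between groups. Chance gives 10% for genes not chosen on the samples, which is no reference for this table. Median-of-ratios scaling was computed over the genes of the table, with factors of 0.933 to 1.07. These could hardly change a sign where the smallest absolute log2 fold change was 0.243, and 0 signs changed. The split of the 684 passing genes moved to 472 higher and 212 lower, so the balance of directions is not settled by these data. The count was 118, 145 and 103 without WT replicates 1, 2 and 3, and 183 without homozygous replicate 1. Of the 41 genes past the threshold that the rule named, 20 kept their call in every fit with 1 replicate left out, among them Col9a1, Col2a1, Prx and Dmp1.

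**Figure D2:**
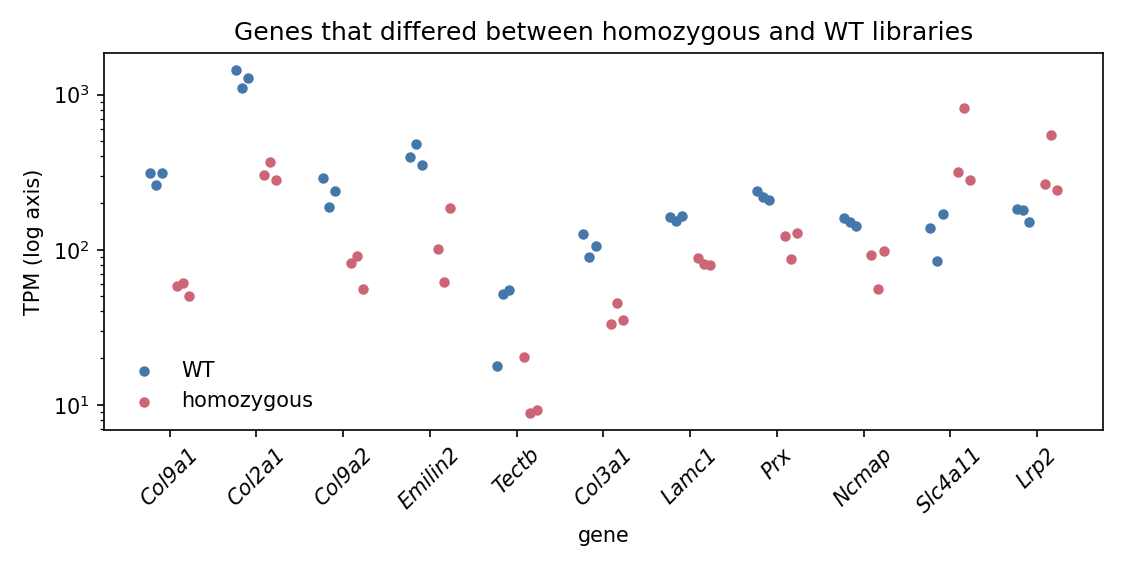
Each point is the TPM of a gene in 1 library on a log axis, with 3 WT and 3 homozygous libraries per gene. The 3 homozygous libraries lie below the 3 WT libraries for Col9a1, Col2a1 and Lamc1 and above them for Slc4a11 and Lrp2; the ranges of Tectb overlap.

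The second comparison asked what the vector treatment changed in the homozygous cochlea. Genes of the interferon response were far higher in both treated samples. Of 22 tested interferon response genes, 20 rose and 22 did when adjusted over the list alone, with a median log2 fold change of 3.64. Ifit3, an interferon-induced gene, rose from 15.5 ± 0.26 TPM (SD, n = 3) to 307 ± 69.9 TPM (SD, n = 2), a log2 fold change of 4.20 (limma adjusted p = 0.00107). Zbp1, a nucleic acid sensor, rose from 0.91 ± 0.32 to 111 ± 1.96 TPM (SD, n = 3 and 2). The class II antigen presentation genes H2-Ab1, H2-Eb1, H2-Aa and Cd74 rose with log2 fold changes of 6.94, 6.71, 6.03 and 5.85, and Nlrc5, a regulator of class I genes, with one of 5.37. H2-Q5, H2-Q6, H2-Q7 and Tgtp1 also passed but have near-identical copies and are uncertain. For the interferon list the camera adjusted p was 1.59e-19, and adjusted p = 0.259 with an estimated correlation. Library 3 alone, without libraries 1 and 2, gave 16 of 22 genes higher.

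Markers of macrophages and lymphocytes rose in the same samples. Of 21 macrophage genes 13 rose, and 17 did when adjusted over the list alone, 4 of them being the class II genes above. Of 15 lymphocyte genes 8 rose. Trbc2, a T cell receptor gene, went from 0.44 ± 0.76 to 20.1 ± 2.97 TPM and Cd8a from 0.08 ± 0.14 to 10.3 ± 4.94 TPM (SD, n = 3 and 2). When adjusted over the list alone, 10 lymphocyte genes were higher and 1 lower. Of 11 cytokine and NF-kB target genes 4 rose, and 11 did when adjusted over the list alone, among them Icam1 and Nfkb2 with log2 fold changes of 2.58 and 1.66. Cd8a, Icam1 and Nfkb2 lost their call in 3 of the 6 fits with 1 replicate left out and Trbc2 in 2. Here and below, the fits without treated library 1 or 2 kept the other of the pair and could change few calls. The counts of lost calls therefore understate how often a call failed. The camera adjusted p was 7.55e-13 for macrophages, 2.92e-05 for lymphocytes and 3.08e-06 for cytokines, with adjusted p = 0.259, 0.469 and 0.259 with an estimated correlation. Of 15 neutrophil genes 0 passed limma and 4 had an unadjusted p under 0.05, with S100a9 at 151 ± 158 and 46.6 ± 16.98 TPM and Ltf at 39.4 ± 47.7 and 44.5 ± 19.1 TPM (SD, n = 3 and 2). Most genes of that list lay above 0, 12 against 3 below, with a median log2 fold change of 1.51 (camera adjusted p = 0.124). The median was 1.41 in libraries 1 and 2 and 1.36 in library 3. Of 11 erythroid genes 0 passed limma and 0 had an unadjusted p under 0.05, with log2 fold changes of 0.94 for Hbb-bs and 0.35 for Hba-a1; their median was 0.23 while camera pointed down (adjusted p = 0.73).

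Genes of hair cells mostly lay above 0 without passing. Of 28 hair cell genes 27 had a positive log2 fold change, with a median of 1.02, and 1 rose. That gene was Ush1c, which encodes a stereocilia scaffold protein and went from 22.3 ± 3.58 to 62.6 ± 11.9 TPM (SD, n = 3 and 2; limma adjusted p = 0.0331). When adjusted over the list alone, 7 hair cell genes rose. By camera the hair cell list had an adjusted p of 7.49e-05, and adjusted p = 0.64 with an estimated correlation. The median of the list was 1.46 in libraries 1 and 2 and 0.67 in library 3, and 0 of its genes passed limma in library 3 alone, where 7 had an unadjusted p under 0.05. Of 22 supporting cell genes 2 rose, Otog and Lfng with log2 fold changes of 2.05 and 1.68, against 7 higher and 2 lower when adjusted over the list alone. Of these 22 genes 14 lay above 0, and the camera adjusted p was 0.73. Of 16 otic matrix genes 2 rose, Otog and Ceacam16 (log2 fold change 1.21), against 5 higher and 2 lower when adjusted over the list alone. Otic matrix genes lay above and below 0 in equal number, 8 each (camera adjusted p = 0.969). Of 29 junction genes 3 rose, among them the claudin gene Cldn3 and Tjp3 with log2 fold changes of 2.49 and 2.11. When adjusted over the list alone 13 were higher and 1 lower, and the camera adjusted p was 0.000132, with adjusted p = 0.469 with an estimated correlation. Junb was the 1 of 14 immediate early genes that rose, by 2.32 on the log2 scale, and P2rx2 the 1 of 11 basal, root and spindle cell genes, by 1.06. Ush1c, Lfng, Ceacam16, Tjp3 and P2rx2 lost their call in 3 of the 6 fits with 1 replicate left out, and Otog and Junb in 2.

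Mitochondrial transcripts, bone genes and myelin genes lay mostly below 0, and few passed singly. Below 0 were 13 of 13, 14 of 14 and 16 of 18 tested genes of these lists. Mitochondrially encoded genes made up 13.6%, 10.7% and 13.3% of TPM in the homozygous libraries and 2.16%, 2.21% and 6.14% in the treated libraries. Of 13 such genes 3 fell and 11 did when adjusted over the list alone, among them mt-Nd2, mt-Nd4 and mt-Nd6 with log2 fold changes of -3.70, -3.25 and -3.89, although reads of mitochondrial genes can be shared with nuclear copies. For these genes the camera adjusted p was 2.53e-09, with adjusted p = 0.585 with an estimated correlation. Of 24 nuclear genes of oxidative phosphorylation 3 fell, and 6 did when adjusted over the list alone, among them Ndufa4 (-2.12) and Cox5a (-1.77). Their camera adjusted p was 5.77e-06, with adjusted p = 0.64 with an estimated correlation and 0.21 with fry. Their median was -0.82 in libraries 1 and 2, which carried forebrain transcripts, and -0.22 in library 3. Of 14 bone genes 2 fell, and 3 did when adjusted over the list alone. Ibsp, the gene of bone sialoprotein, went from 144 ± 94.3 to 17.5 ± 2.79 TPM (SD, n = 3 and 2), and Mepe was at 10.5, 19.4 and 6.31 TPM in homozygous libraries and at 0, 0 and 0.0168 TPM in treated libraries. Of 18 Schwann cell and myelin genes 1 fell, which was Mog (log2 fold change -3.70), a gene of central myelin, and 6 fell when adjusted over the list alone. The camera adjusted p was 3.08e-06 for bone and 1.74e-05 for myelin, with adjusted p = 0.598 and 0.64 with an estimated correlation. With fry the adjusted p was 0.147 for the mitochondrially encoded genes, 0.21 for bone and 0.272 for myelin, so these lists did not pass. Less bone and nerve in the dissected tissue was not tested as a cause in this comparison. Of 21 spiral ganglion neuron genes 2 fell, the neurofilament genes Nefl and Nefh with log2 fold changes of -1.41 and -1.39, and the camera adjusted p was 0.0166, with adjusted p = 0.834 with an estimated correlation. The median of this list was 0.14 in libraries 1 and 2 and -0.78 in library 3. Its call was lost without library 3 (adjusted p = 0.664), without homozygous replicate 3 (0.0727) and with fry (0.547). Otos was the 1 of 13 fibrocyte genes that fell, by 1.67 on the log2 scale. With 1 replicate left out Nefh lost its call in 4 of 6 fits, Ibsp in 2 and each of the other genes named as lower here in 3.

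In the remaining lists few genes passed. Tnnc2, listed at 0 in the 3 treated libraries and at 2.60, 4.60 and 3.27 TPM in the homozygous libraries, was the 1 of 8 skeletal muscle genes that fell, and the list had a camera adjusted p of 0.0154, with adjusted p = 0.569 with an estimated correlation. Of 26 extracellular matrix genes 0 passed limma and 5 had an unadjusted p under 0.05, with Sparc at 3550 ± 313 and 1790 ± 396 TPM and Bgn at 426 ± 138 and 337 ± 35.1 TPM (SD, n = 3 and 2). That list had a camera adjusted p of 0.0197, with adjusted p = 0.675 with an estimated correlation, and like the muscle list it lost its call without treated library 3 (adjusted p = 0.114 and 0.0961) and with fry (0.445 and 0.142). Without homozygous replicate 2 the matrix list also lost its call (adjusted p = 0.159). Stria marginal cells (15 genes tested), intermediate cells and melanocytes (13), endothelium (14), p53 targets (12), unfolded protein response (15) and cell cycle (20) each had 0 genes past the threshold of limma. In that order 2, 1, 4, 2, 6 and 6 of their genes had an unadjusted p under 0.05, and adjusted over the list alone 3 genes of the unfolded protein response were higher and 0 of the others passed. Their genes with the highest means included Lrp2 (log2 fold change 0.84), Slc12a2 (-0.51), Dct (0.30), Gsta4 (0.44), Emcn (0.60), Rgs5 (-0.51), Ei24 (0.65), Mdm2 (-0.57), Calr (0.23), Hsp90b1 (0.03), Pcna (-0.71) and Mcm2 (-0.14). Unlike Pcna and Mcm2, most cell cycle genes lay above 0, 16 against 4 below, with a median of 0.51 (camera adjusted p = 0.143). The endothelium list had a median of -0.04 and a mean of 0.06, with camera pointing down (adjusted p = 0.579). Other genes among the largest falls were Sh3bgr (-4.23), Smim26 (-3.51) and A2ml1 (-3.40). These and Tnnc2 lost their call in 3 of the 6 fits with 1 replicate left out, and Klk6 in 2. Klk6 was listed at 0 in the 3 treated libraries and at 38.6, 10.1 and 32.0 TPM in the homozygous libraries. H4c18, a histone gene with near-identical copies, was also listed at 0 in the treated libraries and is uncertain.

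Of the 17102 tested genes 754 passed, 589 higher and 165 lower in the treated samples, and 4574 had an unadjusted p under 0.05. The median log2 fold change of all genes was 0.20. Median-of-ratios scaling moved it by 0.175 to 0.0212, and 404 higher and 243 lower genes then passed. The treated libraries differed from each other in tissue markers. Camk2a, a forebrain gene named after its values were seen, was at 745, 722 and 8.13 TPM in treated libraries 1, 2 and 3 and below 1 TPM in the homozygous libraries. The count was 222 genes without libraries 1 and 2, 2984 without library 3, and 63, 183 and 70 without homozygous replicates 1, 2 and 3. Of the 41 genes past the threshold that the rule named here, 12 kept their call in every fit with 1 replicate left out, among them Ifit3, Zbp1, Cd74 and Nlrc5. Those fits include the ones without treated library 1 or 2, which removed no sample and gave 728 and 745 genes. Of the 13 lists past camera the 5 of interferon, macrophages, lymphocytes, cytokines and junctions also passed fry.

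**Figure D3:**
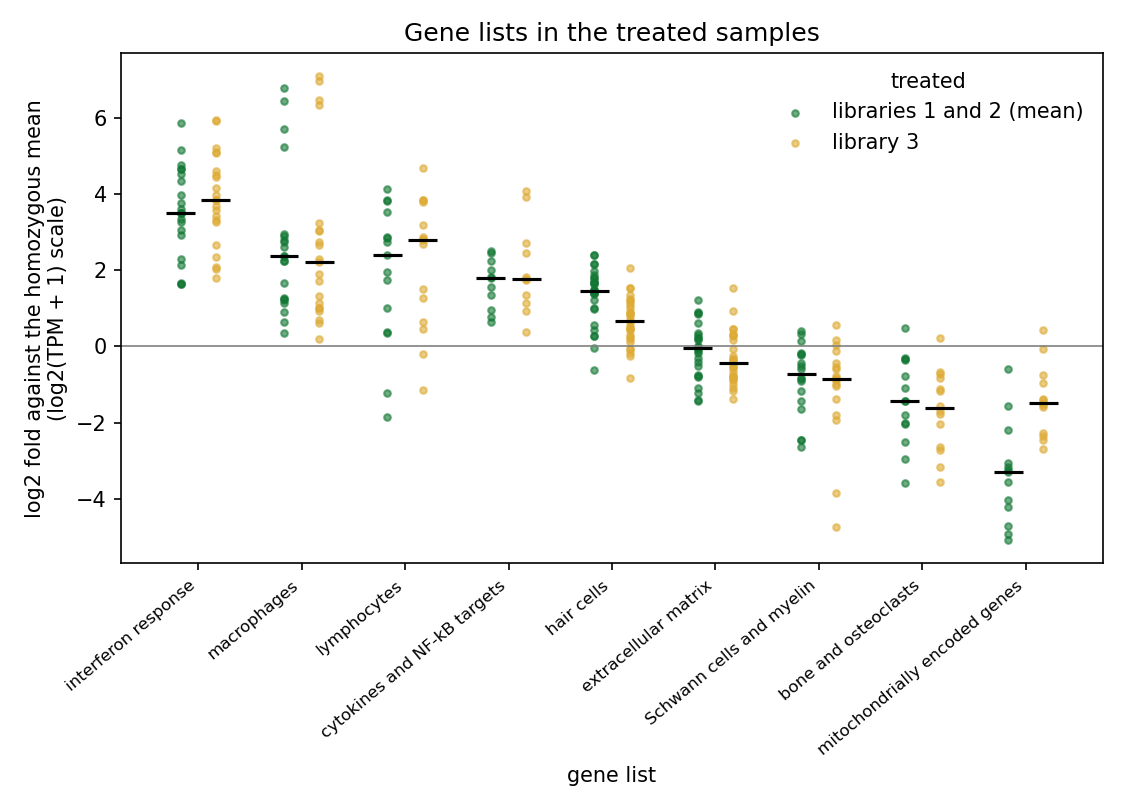
Points are the log2 fold changes of the tested genes of 9 fixed lists against the homozygous mean, for the mean of treated libraries 1 and 2 and for treated library 3, with black lines at the medians. The interferon list has a median of 3.51 in libraries 1 and 2 and 3.84 in library 3; the mitochondrially encoded genes have medians of -3.30 and -1.47.

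The third comparison asked whether the treatment moved genes back from the homozygous toward the WT level. Of the 642 genes that passed between homozygous and WT and were tested in both tables, 344 or 53.6% had a fold change of the opposite sign after treatment. Simulated treated groups that were unchanged, with the differences from WT kept, gave 50% with a 95% range of 46.4% to 54%. The kept differences were the fitted ones, which hold noise of the shared homozygous libraries. Simulations with noise alone gave 73% among as many top genes, with a 95% range of 69.3% to 76.6%. By these simulations the share without any return may lie between 50% and 73%. Neither held an overall shift, although 61% of all tested genes lay above 0 after treatment. Of the 642 genes 418 were lower and 224 higher in homozygous libraries, so such a shift alone can raise the share. The observed share was 58.4% in libraries 1 and 2 and 46.1% in library 3. Of the genes lower in homozygous libraries 54.8% lay above 0 after treatment, while 61% of all genes did. Of those higher in homozygous libraries 51.3% lay below 0, while 39% of all genes did. The covariance of the log2 fold changes over the 1273 genes was -0.036, against -0.0403 in simulated unchanged groups (95% range -0.048 to -0.0332). That range came from noise alone. Real differences in both comparisons would widen it, so it cannot decide. The correlation across genes, which are not independent replicates, was -0.0586. Simulations with noise alone gave -0.414 (95% range -0.471 to -0.359), but they left out the real differences, which widen the fold changes and draw a correlation toward 0. Genes past the threshold in both comparisons numbered 15 with opposite and 12 with the same direction. Lower and then higher were 12 genes, higher and then lower 3, both lower 6 and both higher 6. Independent overlap would give 11.8, 3.17, 5.91 and 6.33 in that order, and these counts were not tested. The 23 matrix genes of both matrix lists in the first table had a median log2 fold change of -0.98 between homozygous and WT and of -0.15 between treated and homozygous. No test was made for each direction alone. The share over both directions lay inside the range with the differences kept, near its upper end, and below the range with noise alone. It was 61.5%, 55.6% and 52.9% without WT replicates 1, 2 and 3 and 48.8%, 58.8% and 49.5% when homozygous replicate 1, 2 or 3 was left out of the first comparison. Those fits had no simulated range of their own, and neither range allowed for the overall shift after treatment. Whether the share exceeds chance is therefore not settled. With 2 treated samples, a partial return of some genes is not excluded. Treated and WT libraries were not compared, because they stood in tables with different values for the same homozygous libraries.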

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

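Median-of-ratios scaling, robust moderation, the filter of 5 TPM, the 6 columns of the second table as separate samples, treated libraries 1 and 2 left out, removal of mitochondrial genes and removal of the length trend were chosen after seeing the data. No named gene past the threshold changed sign under any alternative run. Over single genes and lists, 1061 values kept their side of the threshold and 270 lost it. The direction of Mpzl2 was kept throughout. For homozygous against WT the 692 genes became 140 with a log2 fold threshold of 1 and 343 with a replicate block, where Sox8, Apod, Stmn2, Arc, Spp1, Oas1a, Bbc3 and Manf no longer passed, and ranged from 103 to 611 when each replicate was left out. The share of passing genes that were higher turned from 34.8% to 69% under median-of-ratios scaling, because a shift of the whole scale decides which genes of a list without small changes pass. Leaving out each replicate gave log2 fold changes of -1.46 to -1.04 for Mpzl2, with an adjusted p of 0.0544 without WT replicate 3. For treated against homozygous the 754 genes became 134 without a filter on low values, of which 94.8% were higher, with 25579 genes tested. The 6 columns as separate samples gave 3563 genes, and the replicate block, fitted to those columns, 1485, where the spiral ganglion neuron list had a camera adjusted p of 0.0629. Leaving out treated libraries 1 and 2 together gave 222 genes, and leaving out each replicate gave 63 to 2984, with 75.4% to 98.4% of them higher. A fit that left 1 treated sample assumed that it varied like the homozygous libraries. The share that was higher was 78.1% as reported, 62.4% under median-of-ratios scaling and 60.6% with the length trend removed. The 3 and 13 lists past the threshold became 0 and 0 with an estimated correlation and 5 and 5 with fry. The share of opposite signs after treatment moved by less than the difference between the treated samples under every alternative. That bound is wide, since the share still ran from 46.1% without treated libraries 1 and 2 to 61.5% without WT replicate 1. Fits that left 1 treated sample gave the values that set the bound, so they could not exceed it. Apart from the cases with fewer samples, more genes or another scale, the cause was not tested.

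The replicate numbers did not pair the samples. Deviations from the group means of same-numbered libraries had correlations across genes of 0.0493, -0.14 and -0.0743 in the first table and 0.0304, -0.146 and -0.117 in the second, and not every library correlated best with its own number. Count-based tests, size factors in place of other count scaling, a filter on 10 reads, transcripts in place of genes and all alternatives for treated against WT were not run, because the values are TPM per gene in 2 separate tables. Values as deposited are scaled to the library total, and each table's fit holds only the 2 groups compared. With depth unknown, its limit on low genes cannot be given.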

Other observations

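The tests of forebrain tissue, scaling, immune cells and sex for the interferon genes, of spiral ganglion neurons, and of bone, nerve and scaling for the matrix genes were chosen after the results had been seen. The held-out forebrain list and the splits of the samples were fixed before their results were seen. Explanations for the fall of mitochondrial transcripts were not tested. Genes named below that the rule did not name were chosen after their values were seen, except the held-out forebrain list.

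Genes past the threshold in both comparisons, named here after their values were seen, included Ibsp, Mgp, Nefl and Chgb, which were lower in homozygous than in WT libraries and lower again in treated samples. Their log2 fold changes were -1.59, -0.90, -0.64 and -0.63 in the first comparison and -2.79, -1.30, -1.41 and -2.03 in the second. Oas1a and H2-K1 were higher in both, with 0.84 and 0.46 in the first and 3.60 and 4.11 in the second. Gata2, Agrn, Chadl and Rnf213 were lower in homozygous libraries and higher in treated samples, with -0.83, -0.58, -1.25 and -0.62 in the first and 0.88, 1.27, 1.91 and 2.25 in the second. The comparisons share the homozygous libraries, and the numbers of such genes were close to those of independent overlap.

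Sex-linked genes divided the libraries of the second table in another way than the groups. Xist, the RNA of the inactive X chromosome, was at 162, 0.62 and 0.91 TPM in homozygous libraries 1, 2 and 3 and at 124, 129 and 171 TPM in treated libraries 1, 2 and 3. Ddx3y, a Y-linked gene, was at 0.50, 49.5 and 50.3 TPM and at 23.0, 18.8 and 0.0858 TPM. Treated libraries 1 and 2 therefore held both, and sex was not balanced between the groups. Malat1, a nuclear RNA, was at 25734, 22295 and 21924 TPM in homozygous and at 9142, 9725 and 8821 TPM in treated libraries.

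Interferon response genes were higher in both treated samples. Forebrain tissue in treated libraries 1 and 2 is argued against as the whole cause, since the median log2 fold change of the list was 3.84 in library 3, where the held-out forebrain genes had a median of -0.06. Scaling after the fall of mitochondrial transcripts is argued against by a median of 3.46 under median-of-ratios scaling. A gain of immune cells of the kind already present would raise H2-K1 and H2-D1, which most cells make, no more than the leukocyte gene Ptprc, but both rose by at least 1.59 more on the log2 scale in each treated sample. Sex as the whole cause is argued against, since treated library 3 and homozygous library 1, both female by Xist and Ddx3y, differed by a median of 4.32 (SD 1.16 over 22 genes) on the log2 scale. Homozygous library 1, the only female one, lay 0.431 below the male libraries (SD 0.647). A response of the tissue to the vector or editor, recruited cells of another state, an infection and a difference in handling between groups stay open and were not tested, since no injected control was analysed here.

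Forebrain transcripts were present in treated libraries 1 and 2. Of 16 held-out forebrain genes 13 had a log2 fold change above 1 there, with a median of 2.97, against 3 in library 3; 6 of the 16 were at 10 TPM or more in the homozygous libraries, and 4 of those 6 were among the 13. Brain tissue carried into the sample may account for these genes. The glial genes Gfap, Mobp and Mog did not rise, with log2 fold changes of -0.257, -2.45 and -2.65 in libraries 1 and 2 and -3.05, -3.84 and -4.74 in library 3. In libraries 1 and 2 Gfap was at 63.2 and 62.0 TPM, Mobp at 45.1 and 47.6 and Mog at 3.29 and 3.25. Library 3 had 8.20, 17.05 and 0 TPM. These levels cap what brain tissue could have brought, and the homozygous levels, 14.7 to 489 TPM, could hide a small share. How much of each gene a share of brain brings is not known from these data, so the glial genes neither support nor exclude a small one. More spiral ganglion neurons than in the homozygous libraries are argued against by 6 genes of neurons in general. Snap25, Uchl1, Thy1, Tubb3, Nefl and Nefm had a median log2 fold change of -0.183 (SD 0.715) in libraries 1 and 2. In library 3 they had -0.679, -0.265, -1.13, -1.28, -1.53 and -1.09 in that order. More such neurons than in library 3 are therefore not argued against. Brain neurons make these genes too, so their median in libraries 1 and 2 gives no support to carried-in brain tissue. Altered transcription in neurons stays open and was not tested.

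Matrix genes were lower in the homozygous libraries, a candidate effect of the allele. TPM scaling stays open. The 23 matrix genes had a median log2 fold change of -0.98, and of -0.83 under median-of-ratios scaling. Its factors, 0.933 to 1.07, came from the selected genes of the first table and could hardly move such a median, so this test cannot decide. The fall was larger than the median of -0.363 over all tested genes of that table. Less bone and nerve in the dissected tissue stays open, since the 13 bone and myelin markers in the same table had a median of -0.894, and such a fall could come from dissection or from the allele.

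The number of passing genes was set against other splits of the same samples. For homozygous against WT 1 of the 10 splits gave as many as the real 692 genes, the real one, and the highest of the others gave 5. The genes of the first table are treated as chosen on these samples, so this outcome was fixed in advance and carries no weight. For treated against homozygous 1 of 10 splits gave as many as the real 754, again the real one, and the highest of the others gave 1. With 10 splits no share under 0.05 can be reached.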
